A study of Mus musculus with 2 samples.

How the data were processed

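The series measured total RNA, depleted of ribosomal RNA, from mouse CFU-E cells in 2 libraries, replicate 1 and replicate 2, which the labels place in 1 group. Per the labels, libraries were made by ScriptSeq from 100 ng of RNA. The labelled size ranges were 209 to 891 bases for replicate 1 and 186 to 747 for replicate 2. For each library the authors deposited a gene table and a transcript table on mm10, and the notes deposited with them name GENCODE M4 as the annotation. The quantifier and the aligner are not given in the sources used here; the column names are those that RSEM writes. Per the file headers the tables hold expected counts, which are estimates that share a read matching several genes between them, and TPM, which the authors derived by dividing counts by effective length. Posterior mean TPM and the lower and upper bounds of a credibility interval for TPM stand in further deposited columns. Because TPM divides by effective length, a transcript little longer than a fragment gets a large TPM from few reads, and this affects every share and level given as TPM. The deposited lengths imply a mean fragment of 223.6 bases in replicate 1 and 182.9 in replicate 2. The latter lies below the labelled size range of replicate 2, so that range may not be one of the sequenced fragments.

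The gene tables hold 43346 Ensembl rows, 97 spike-in rows (96 ERCC controls and a phage control) and 26248 rows named only by a number. Spike-in rows had 0 counts in both libraries. Spike-in and numbered rows were left out of scaling and comparisons; the numbered rows held 0 and 25 counts. Symbols, biotypes and coordinates came from GENCODE M21, a later annotation of the same assembly, matched on Ensembl identifiers without their version, and 42462 rows matched while 884 did not. Of the 318 genes in the 23 lists fixed in advance, Ahsp and Snhg1 were not found by symbol. The transcript tables hold 129984 rows.

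Expected counts were rounded to whole numbers for edgeR and DESeq2. Library totals were 62576357 and 36889542 expected counts, and TMM gave effective sizes of 61316286 and 37501366. The biological coefficient of variation is the square root of the common dispersion of an intercept-only model in edgeR 4.0.16, over genes with at least 10 counts in both libraries. DESeq2 1.42.0 gave alternative size factors. R was version 4.3.3, Python 3.11.15, with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Log2 ratios of replicate 1 over replicate 2 used TMM-scaled counts with a prior count of 0.5. Gene levels are TPM, with mean and SD over n = 2. The list comparison was a two-sided permutation test with 100000 resamples on log2(TPM + 0.1) over genes. List differences between replicates were placed among 10000 random lists matched on mean count in 20 bins, using members with a mean count of at least 10. Gene pair ratios were formed within each library, and a denominator of 0 counts was set to 3 counts. No test compared groups, since there is 1 group, and no p-value was given for replicate 1 against replicate 2.

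The gene lists, gene pairs, isoform genes, tests, alternatives and naming rule were fixed before the data were examined. The rule names the 20 genes of highest TPM; the 4 highest members of each list, with up to 6 members of other-lineage lists at 10 TPM or more; every globin, heme and cyclin-dependent kinase inhibitor gene; both genes of each pair; the 10 largest replicate differences each way among protein-coding or named genes with a mean count of at least 50 and non-overlapping credibility intervals; and isoform genes with a major share under 60% or differing by over 15 points. Genes outside that rule are named as such, and some items that the rule covers are not reported here. RNA classes taken from biotypes were added after values were seen. Alternatives covered TPM minimums of 0.5 and 5, pseudocounts, count filters, DESeq2 size factors, posterior mean TPM, CPM from counts and leaving out each replicate.

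Scripts were tested on simulated data. For the dispersion, counts for 10943 genes drawn with a dispersion of 0.04 returned 0.0408, and 196 of 197 genes changed 4-fold passed 2-fold, as did 232 of 9976 unchanged genes. The dispersion estimated from the libraries was higher, at 0.175, so these passing rates do not carry over to them. For the matched lists, 5 of 100 unshifted lists fell outside the central range and 20 of 20 lists shifted by 1 on the log2 scale lay above it, over 12909 genes. Shifts as small as the medians found for the adult globin (0.46) and membrane (0.13) lists were not simulated. The stem and early progenitor median was 1.35. The simulated log2 ratios had the same spread at every mean count. In the libraries the coefficient of variation fell from 125% at mean counts of 10 to 30 to 21.4% at 1000 to 3000. The simulation therefore did not exercise the matching on mean count, and its rates do not carry over to low-count lists such as the stem list. For the permutation test, 8 of 200 pairs of equal lists and 50 of 50 pairs of unequal lists passed 0.05. The unequal lists were drawn further apart than the granulocyte list lay from the membrane list (-2.65). A difference as small as that was not simulated.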

Results

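Total RNA, depleted of ribosomal RNA, was sequenced from mouse erythroid progenitor cells named CFU-E (colony-forming unit erythroid, a committed red cell progenitor defined by the small colonies it forms in culture). The cells came from male C57BL/6J mice aged 5 to 6 weeks. The design held 1 group with 2 biological replicates, each made from 100 ng of RNA, so the questions it answers are which genes these cells expressed and how far the replicates agreed. The labels gave both replicates the same donor identifier and different biosamples, so the spread between them may be partly technical. Gene-level expected counts summed to 62576357 in replicate 1 and 36889542 in replicate 2. Of 43346 Ensembl gene rows, 12716 had reads in replicate 1 and 14415 in replicate 2. Mean gene levels are given with the SD over n = 2, in TPM (transcript abundance scaled for length and library size) unless another unit is named, and coordinates are on mm10. Each SD includes a shift of the whole scale, since nuclear protein-coding genes had a median TPM 1.56-fold higher in replicate 1. With TPM rescaled to those genes, Slc4a1 went from 558 ± 191 to 5613 ± 50.6. Ubtf went from 37.0 ± 0.30 to 395 ± 136. An SD in TPM therefore does not rank genes by how well the replicates agreed. Limits set by a count of 0 use 3 counts per library and cover counting error only, since reads copied by PCR are not independent molecules.

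Short structural RNAs dominated the TPM values. Of the 20 most abundant genes, 11 were small nuclear RNAs of the spliceosome and 3 were the abundant non-coding RNAs Rn7s1, Rn7s2 and Rn7sk, while mt-Co1 and mt-Atp8, which encode subunits of cytochrome c oxidase and ATP synthase, were the only protein-coding genes among them. Rn7s2, an RNA of the signal recognition particle (chromosome 12, 69361182 to 69361481), stood at 58694 TPM in replicate 1 and 75678 in replicate 2, and Rn7sk, which restrains transcription elongation, at 44973 and 23993. The U2 gene copy Rnu2-10 had 11393 and 30143 TPM, and the U1 gene copy Rnu1a1 had 7280 and 24743. The small nucleolar RNA Gm22422 had 107258 and 5387 TPM, and the pseudogenes Gm28437 and Gm28661 had mean levels of 17377 ± 6230 and 17003 ± 12216. Small nuclear RNA genes took 19.6% of TPM in replicate 1 and 52.9% in replicate 2, but 0.59% and 4.61% of expected counts. Small nucleolar RNA genes took 21.1% and 8.65% of TPM, and 0.263% and 0.484% of counts. Nuclear protein-coding genes took 12.4% and 7.49% of TPM, against 46.2% and 46.6% of counts. Mitochondrial genes took 18.4% and 6.07% of TPM and 32.6% and 23.6% of counts, with mt-Co1 alone at 20.98% and 13.75% of counts. Adult globin genes took 2.63% and 1.99% of counts and replication-dependent histone genes 2.13% and 2.47%. The near-identical copies of the 7SL, U1 and U2 genes share reads, so the split between copies is uncertain. The pseudogene Gm28437 had fractional counts, 1994817.2 and 1176605.7, which come from reads shared with other genes. Which genes those were, and where the reads of Gm28661 arose, was not tested. Unprocessed pseudogenes took 7.46% and 7.12% of counts. A gene of 135 bases such as Gm22422 had an effective length of only 2.71 bases in replicate 1, which magnifies its TPM.

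**Figure D1:**
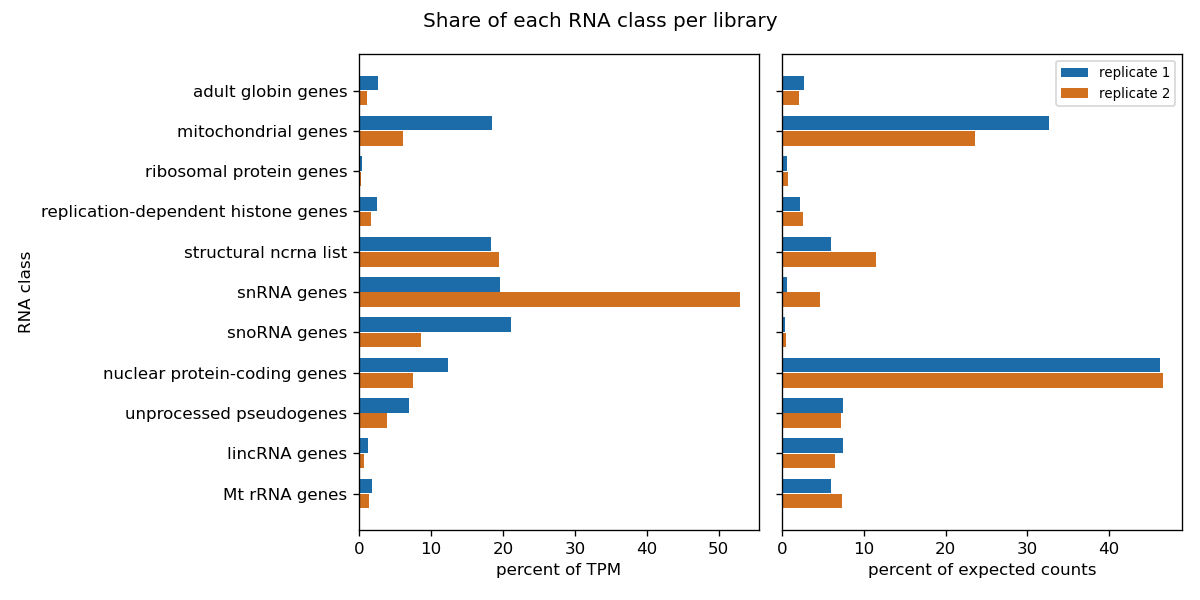
Share of each RNA class in the CFU-E libraries, as percent of TPM on the left and percent of expected counts on the right, with 1 bar per replicate. Small nuclear RNA genes stand at 19.6% and 52.9% of TPM, and nuclear protein-coding genes at 46.2% and 46.6% of counts.

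Across genes the replicates ranked transcripts alike but differed in level for many of them. At a TPM of at least 1 in both libraries, 5632 genes were detected, of which 5152 were protein-coding, 122 processed pseudogenes, 93 small nucleolar RNAs, 38 small nuclear RNAs and 29 long intergenic RNAs. Over the 7564 genes at 1 TPM or more in either library, Pearson's r of log2(TPM + 1) was 0.867 and Spearman's rho was 0.789; these are correlations across genes, which are not independent replicates. Among the 6641 nuclear protein-coding genes of that set r was 0.938. The biological coefficient of variation, the relative spread between replicates that edgeR estimates from counts, was 0.419 over 10943 genes with at least 10 counts in both libraries. It was 0.219 over the 2969 genes with at least 1000 counts in both and 0.960 with no filter over 15292 genes. Detection depended on the scale: 10931 genes had at least 10 expected counts in both libraries before the rounding to whole numbers that gave the 10943 used for edgeR.

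**Figure D2:**
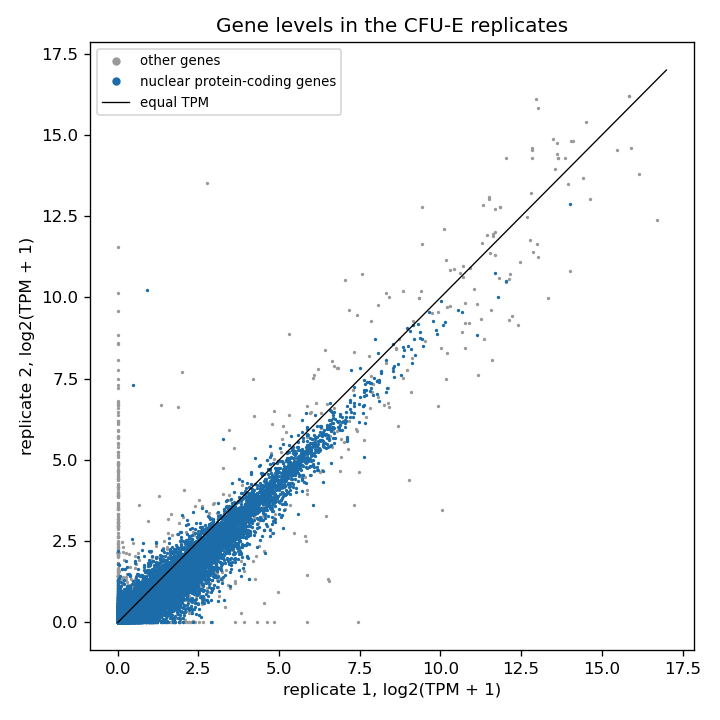
Gene levels in the CFU-E replicates, log2(TPM + 1) of replicate 1 on the horizontal axis and of replicate 2 on the vertical axis, with 1 point per gene. Across the 6641 nuclear protein-coding genes at 1 TPM or more in either library, r was 0.938. The 3384 nuclear protein-coding genes with a mean count of at least 1000 lie mostly under the line of equal TPM. Their median offset is 0.64 on the log2 scale.

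By mean TPM per gene, adult globin genes held the top 3 places among nuclear protein-coding genes, and the embryonic globins were not detectable at this depth. Hba-a2, an adult alpha globin (chromosome 11, 32296489 to 32297298), had 16411.5 and 7587.7 TPM in replicates 1 and 2. The adult beta globins Hbb-bs and Hbb-bt (chromosome 7) had means of 2819 ± 1951 and 2520 ± 1111, and Hba-a1 had 1198 ± 623. In replicate 1 the histone gene Hist2h2aa1, at 3527 TPM, exceeded Hbb-bt, at 3305. Summed with its near-identical copy Hist2h2aa2, it had a mean of 2882, above Hbb-bs and Hbb-bt each. Hba-x, Hbb-y and Hbb-bh1, the globins of primitive red cells, had 0 counts in both libraries, so adult beta-like globin was at least 159958-fold higher than embryonic beta-like globin in replicate 1 and at least 68986-fold higher in replicate 2. Summed alpha globin exceeded summed beta globin 2.41-fold and 2.63-fold in the libraries, a log2 ratio of 1.33 ± 0.09 (0.76 by counts, with no length correction). The log2 ratio of Hbb-bt to Hbb-bs, -0.04 ± 0.43, was within its spread.

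All heme synthesis genes and most genes for iron supply were expressed. All 8 heme enzymes stood above 10 TPM in both libraries, led by Alas2, the erythroid enzyme that commits glycine and succinyl-CoA to heme (chromosome X, 150547375 to 150570638), at 215 ± 61.2. Cpox had 82.4 ± 26.5, Ppox 78.4 ± 39.3, Urod 68.0 ± 4.69, Fech 59.6 ± 18.1, Uros 33.8 ± 11.7 and Alad 33.5 ± 3.85. Alas2 exceeded its housekeeping counterpart Alas1 by a log2 ratio of 6.66 ± 0.74. Among 18 iron genes 15 were at 1 TPM or more in both libraries, led by Tfrc, the transferrin receptor, at 249 ± 50.1. The ferritin chains Fth1 and Ftl1 had 237 ± 127 and 102 ± 39.1. Slc25a37 (mitoferrin 1), the mitochondrial iron importer of red cell precursors, had 146 ± 64.3 and exceeded its paralog Slc25a28 by a log2 ratio of 7.88 ± 1.498 (9.66 by counts).

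Membrane and cytoskeletal genes of the red cell were abundant. All 18 members were at 1 TPM or more in both libraries and 16 at 10 or more, with a median level of 93.8. Slc4a1, the band 3 anion exchanger (chromosome 11, 102348824 to 102366203), had 558 ± 191, and Sptb, which encodes a spectrin chain, had 161 ± 52.1. In the list of late maturation genes 16 of the 17 that were matched were at 1 TPM or more in both libraries. The highest were Trim10 at 49.9 ± 10.3, Tspo2 at 47.8 ± 32.9, Ypel4 at 36.8 ± 9.66 and Fn3k at 32.8 ± 12.3.

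Erythroid transcription factors were expressed, while genes of stem and early progenitor cells were low. Of 16 erythroid regulators 15 reached 1 TPM in both libraries, led by Sox6 at 69.1 ± 17.1, Lmo2 at 40.2 ± 11.4, Nfe2 at 38.5 ± 15.3 and Zfpm1, the Gata1 cofactor, at 37.8 ± 1.33. Gata1, a master regulator of the lineage (chromosome X, 7959260 to 7978071), had 14.9 ± 6.75 and Klf1 36.1 ± 24.4. Gata1 exceeded Gata2, its counterpart in earlier progenitors, 75.6-fold and 92.0-fold in the libraries, and exceeded Spi1, a myeloid regulator, by a log2 ratio of 2.38 ± 0.25. Klf1 exceeded the megakaryocyte regulator Fli1 by a log2 ratio of 4.40 ± 0.70. By counts, with no length correction, these log2 ratios were 5.39 for Gata1 to Gata2 (6.38 by TPM), 2.96 for Gata1 to Spi1 and 3.18 for Klf1 to Fli1. None of the 16 stem and early progenitor genes reached 1 TPM in both libraries, the highest being Erg at 0.64 ± 0.63, Cd34 at 0.51 ± 0.23, Meis1 at 0.30 ± 0.23 and Hoxa9 at 0.30 ± 0.42. In replicate 1 alone 1 did, Erg at 1.08, and 5 of the 16 reached that level in both libraries once TPM was rescaled to nuclear protein-coding genes.

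Kit was low in both libraries. Kit, the stem cell factor receptor (chromosome 5, 75574916 to 75656722), had 345 and 328 counts, or 0.42 and 0.51 TPM, and 8079 and 6836 nuclear protein-coding genes were higher. Its log2 ratio to Cd34, -0.04 ± 0.89, was within its spread, but was 0.93 by counts and 0.11 by posterior mean TPM. Epor, the erythropoietin receptor, had 17.0 ± 7.03 and stood among the 6 of 16 signalling genes at 1 TPM or more in both libraries, with Pik3r1 at 20.96 ± 2.89, Jak2 at 9.14 ± 2.43 and Bcl2l1 at 8.82 ± 1.94. Bcl2l1, an inhibitor of apoptosis, exceeded Bcl2 by a log2 ratio of 5.86 ± 0.32 and lay below Mcl1 by a log2 ratio of -0.47 ± 0.07. Stat5a lay below Stat5b by a log2 ratio of -0.65 ± 0.34. By counts the log2 ratios of Bcl2l1 to Bcl2, Bcl2l1 to Mcl1 and Stat5a to Stat5b were 4.12, -1.26 and -1.13. With TPM rescaled to nuclear protein-coding genes, 13 of the 16 signalling genes reached 1 TPM in both libraries, with Kit at 5.10 ± 2.43 and Epor at 169 ± 11.4. These ratios rest on 2 libraries and were not tested.

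Among the lists of other lineages, granulocyte genes stood highest. Of 17 granulocyte genes 14 were at 1 TPM or more in both libraries and 10 at 10 or more, with a median of 14.8. S100a8 and S100a9, which encode the calprotectin chains of neutrophils, had 405 ± 215 and 225 ± 70.6, and the granule genes Ngp, Camp, Mpo and Ltf had 125 ± 75.7, 50.7 ± 15.1, 47.0 ± 28.5 and 24.1 ± 4.02. In the monocyte and macrophage list 11 of 17 reached 1 TPM in both libraries. Lyz2, which encodes lysozyme, had 82.9 ± 29.0, Vcam1 8.59 ± 2.11, C1qb 5.03 ± 1.61 and Cd68 4.73 ± 2.34. The mast cell, basophil and eosinophil list had 4 of 11 members at that level, led by Prg2 at 13.5 ± 4.02, Mcpt8 at 5.48 ± 1.252, Prss34 at 4.21 ± 1.26 and Cpa3 at 2.60 ± 1.67. The B cell list had 5 of 14, led by Ighm at 20.3 ± 8.65 and Cd79b at 4.22 ± 2.72. The megakaryocyte list had 3 of 17, with Itga2b at 3.11 ± 2.11 and Vwf at 3.04 ± 2.09; the T and NK cell list had 2 of 14, with Cd3g at 1.60 ± 0.60; and the endothelial and stromal list had 1 of 12, Cxcl12 at 2.67 ± 1.01. These counts depend on the scale and the library: B cell, megakaryocyte, and endothelial and stromal genes at 1 TPM or more numbered 8, 5 and 2 in replicate 1 alone, and 13, 7 and 6 in both libraries with TPM rescaled to nuclear protein-coding genes. On that scale the T and NK cell list had 10 of 14 members at 1 TPM or more in both libraries, the mast cell, basophil and eosinophil list 8 of 11, the monocyte and macrophage list 16 of 17 and the granulocyte list 15 of 17. In a two-sided permutation test of mean log2(TPM + 0.1) over genes, with 100000 resamples and Benjamini-Hochberg adjustment over the 8 lists, each list lay below the red cell membrane list, as it also did in each library alone. The difference was -2.65 for granulocytes (adjusted p = 0.002), -4.95 for monocytes and macrophages and -8.39 for stem and early progenitor genes (adjusted p = 1.1e-05 each in the permutation test, from the smallest p of 1e-05 that the resamples can give). Genes of a list are not independent replicates, so these p-values describe the lists as fixed and not a population of samples. The result holds for the membrane list alone, since other red cell lists were not compared. The granulocyte median of 14.8 TPM was near those of erythroid regulators (11.8), late maturation (15.2) and iron handling (15.7), and below heme synthesis (73.2).

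**Figure D3:**
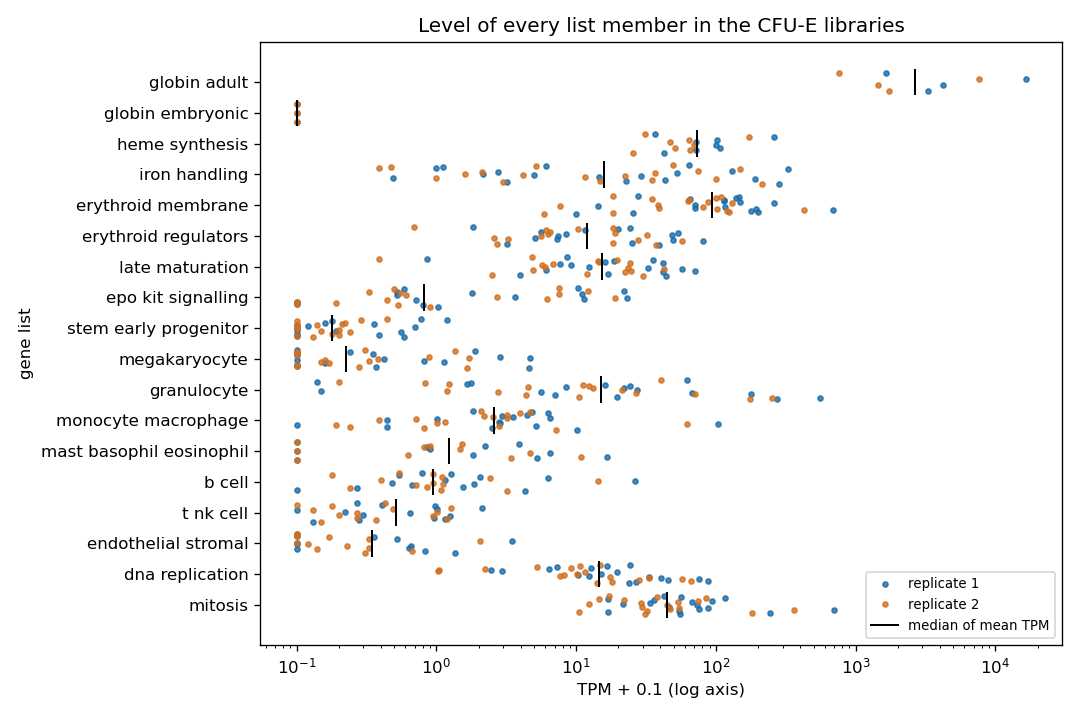
TPM of every member of the lineage, signalling and cell cycle gene lists in the CFU-E libraries, on a log axis after adding 0.1, with 1 point per gene and replicate and a bar at the list's median. The red cell membrane list has a median of 93.8 and the granulocyte list one of 14.8.

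Cell cycle genes were abundant. All 18 mitosis genes were at 10 TPM or more in both libraries, with a median of 44.9. Mki67, a proliferation marker (chromosome 7, 135689784 to 135716361), had 532 ± 242, Top2a, the topoisomerase of dividing cells, 212 ± 44.1, Birc5 101 ± 22.6 and Ccna2 83.2 ± 13.5. Of 18 DNA replication genes 16 reached 1 TPM in both libraries, led by Rrm2 at 77.3 ± 15.2, Pcna at 66.1 ± 12.9, Mcm7 at 36.9 ± 5.12 and Rrm1 at 36.7 ± 12.4. Replication-dependent histone genes, whose messages lack a poly(A) tail and are kept by total RNA sequencing, made up 28 of the 50 most abundant nuclear protein-coding genes, and 59 of 67 reached 1 TPM in both libraries. Among inhibitors of cyclin-dependent kinases, Cdkn2c had 22.0 ± 6.07, Cdkn2d 18.9 ± 3.22 and Cdkn1b 11.6 ± 5.80. Cdkn1a had 94 and 0 counts, and Cdkn1c, Cdkn2a and Cdkn2b had 0 in both libraries.

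In the lists for growth, stress and glycolysis the number of genes reached depended on the scale. Of 14 ribosome biogenesis genes 8 reached 1 TPM in both libraries, led by Npm1 at 42.4 ± 17.8, Ubtf at 37.0 ± 0.30, Nop58 at 21.1 ± 17.3 and Ncl at 18.3 ± 6.18. In the immediate early and stress list 6 of 15 did, with Btg2 at 28.8 ± 8.63 and Ddit3 at 16.3 ± 8.92 far above Fos at 1.98 ± 1.22. In the hypoxia and glycolysis list 6 of 15 did, with Hk1, a hexokinase, at 28.6 ± 10.3 and Pkm at 7.59 ± 2.93. Pkm exceeded Pklr, the other pyruvate kinase gene, by a log2 ratio of 3.68 ± 0.04 (3.41 by counts). With TPM rescaled to nuclear protein-coding genes, all 14 ribosome biogenesis genes, 11 of 15 immediate early and stress genes and 11 of 15 hypoxia and glycolysis genes reached 1 TPM in both libraries.

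Between the replicates, adult globin and red cell membrane genes were higher in replicate 1. All 4 adult globin genes were higher there, by a median log2 ratio of 0.46 after TMM scaling, at percentile 99.7 among 10000 random lists matched on expression. Summed alpha and summed beta globin were higher by log2 ratios of 0.38 and 0.59. The genes are paralogs in pairs, while random lists draw each gene separately, so the percentile may overstate how unusual the globin list is. Membrane genes were higher in 12 of 18 cases with a median of 0.13, at percentile 97.8. Of 12 stem and early progenitor genes measured, 9 were higher in replicate 1, with a median of 1.35 at percentile 99.8, but at fewer than 1000 counts per gene and library. These 3 lists lay outside the central range of 2.5 to 97.5, and the other 19 lists measured did not, with iron handling at 3.37 and structural RNAs at 3.09. On the deposited TPM ratio the membrane and stem lists moved inside that range, at 95.2 and 95.4, while iron handling (1.86) and megakaryocyte genes (98.1) moved outside it. Structural RNAs moved outside at a mean count of at least 100 (0.11) and against nuclear protein-coding genes alone (1.34). Only adult globin genes lay outside under every setting. With 1 library on each side these percentiles describe the libraries and have no replicate check.

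Of 10403 genes with a mean count of at least 50, 1104 were at least 2-fold higher in replicate 1 and 1088 in replicate 2. On the TPM ratio the split became 3237 and 585 on a scale where nuclear protein-coding genes as a whole were lower in replicate 2 by a median of 0.64 (log2, over the 3384 genes with a mean count of at least 1000). By scaled counts with no filter on low counts (a mean of at least 1), 2099 of 14869 genes were at least 2-fold higher in replicate 1 and 4001 in replicate 2. At a mean count of at least 1000 the numbers were 36 and 86 of 3587 genes. The 10 named genes highest in replicate 1 had 0 counts in replicate 2, among them Cdon with 172 counts, Hoxa9 with 163 and Egf with 157, and Hist2h3c1 with 588.2 and Galnt2 with 349.17, whose fractional counts come from reads shared with other genes and leave their differences uncertain. Of the 10 highest in replicate 2, 8 had 0 counts in replicate 1, among them the small nucleolar RNA Snora15 with 797 counts (at least 434-fold), Abcc3 with 260 (at least 141.7-fold), Agbl3 with 202 and Phospho1 with 176. The other two were the histone genes Hist1h2ao and Hist2h2aa2. Hist2h2aa2 had 43.3 and 63021 counts, while its near-identical neighbour Hist2h2aa1 had 209474 and 62837, and their sum differed by a log2 ratio of only 0.03, so the split of reads between the copies is uncertain.

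Transcript tables gave the share of each gene's TPM in its most abundant annotated transcript. Of 25 genes examined 11 had at least 90% in that transcript and 10 had under 60%. Alas2 had 55.6% ± 1.56 in Alas2-201, and a short retained-intron transcript, Alas2-203, held 19.4% and 30.01% in the replicates. For Bcl2l1 the most abundant transcript was Bcl2l1-205, at 43.2% ± 7.05, but Bcl2l1-201 held 0.98% in replicate 1 and 36.1% in replicate 2. Gata1 had 79.6% and 95.6% in Gata1-201. Ikzf1, which encodes Ikaros, had 89.9% and 55.1% in its major transcript, and Kit had 100% and 84.0%. Epb41, Ank1 and Nfe2 were spread over many transcripts, with major shares of 32.0% ± 4.21, 30.1% ± 4.46 and 30.1% ± 6.36. Bcl11a had 40.3% ± 8.80 in a retained-intron transcript and Runx1 44.7% ± 8.10 in a non-coding one; Tfrc had 55.2% ± 6.85 and Bnip3l 48.7% ± 3.70. By share of expected counts, which are not divided by length, the same transcripts held 89.9% for Bnip3l, 82.3% for Tfrc, 78.3% for Alas2, 35.4% for Ank1, 33.6% for Runx1, 20.4% for Epb41 and 15.2% for Nfe2. By that share Kit had 98.7%, Gata1 98.2% and Ikzf1 91.0%, while by posterior mean TPM Kit had 57.8%. The lower TPM share of Kit in replicate 2 rests on 8.42 counts of Kit-205, a retained-intron transcript, and that of Gata1 in replicate 1 on 130.99 counts of Gata1-203, of 421 bases. Gata2, at 122 and 52 counts in the replicates, had 100% and 0% in the same transcript.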

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

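The reading below was made only after its values were seen. Outside the gene and transcript rows used in the report, the rows named only by a number held 25 counts in replicate 2, above the 3 counts that a count of 0 allows, and 0 in replicate 1. These 25 counts lay in 2 of 26248 rows, with 16 and 9 counts. The spike-in rows had no reads in either library. No explanation was tested for them.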

How the results depend on the processing

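Leaving out a replicate leaves 1 library, so the correlation, the biological coefficient of variation and the replicate differences have no such value, and with n = 2 a single library always lies within 1 SD of the mean. Alternatives chosen after seeing the data were the rescaling of TPM to nuclear protein-coding genes, the minimum of 1000 counts, and the restriction to nuclear protein-coding genes. A count, and a statistic with no SD of its own, was taken as moved past a factor of 1.5. No paired analysis was possible because there is 1 group. Posterior mean TPM was not run for ratios with a denominator of 0 counts.

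All 8 other-lineage lists stayed below the membrane list past the threshold with a pseudocount of 1, with medians and in each library alone. The number of genes detected was 2154 at a TPM minimum of 5, 10931 by at least 10 counts and 10051 with rescaled TPM, and ran from 6115 to 7081 in single libraries. The biological coefficient of variation was 0.960 with no filter and 0.219 at 1000 counts. Genes differing 2-fold numbered 6100 with no filter (2099 higher in replicate 1 and 4001 in replicate 2), 753 at a mean of 200, 122 at a mean of 1000 and 3822 by TPM ratio. Filters by count and by a TPM minimum test different numbers of genes. The TPM ratio covered the same 10403 genes as the main setting. Its median log2 ratio over them was 0.660, against 0.018 with TMM-scaled counts, so the whole scale was shifted. Other causes were not tested. By share of expected counts in place of TPM, mitochondrial genes had 28.1%, ribosomal protein genes 0.653%, the structural RNA list 8.68%, small nuclear RNA 2.60%, small nucleolar RNA 0.373%, nuclear protein-coding genes 46.4%, long intergenic RNA 6.93%, mitochondrial ribosomal RNA 6.60%, the miscellaneous RNA class 6.64%, the 10 most abundant genes 25.1% and the 100 most abundant 54.7%, since counts are not divided by length. Most of the long intergenic RNA share, 7.365% and 6.49% of counts in replicates 1 and 2, lay in 1 gene outside the naming rule. That gene, Gm26917, held 5.64% and 4.45% of counts. It stands in this class by its annotated biotype alone, and which RNA its reads came from was not tested. The share may therefore not be one of long intergenic RNA. The correlation ran from 0.760 with a pseudocount of 0.1 to 0.938. Among single values, 11 of 15 pair ratios and 12 of 25 isoform shares moved by over 1 SD on counts, 10 of 23 lists changed their number of members at 1 TPM by over 1.5 times with rescaled TPM, and none changed sign as a called value. Pairs with the higher numerator numbered 10 to 12 and isoform genes under 60% numbered 8 to 11 in single libraries, and 3 or 4 lists lay outside the central range under each setting, but their members changed and only the adult globin list was among them every time. Without replicate 2, 4 of 23 lists changed their number of members at 1 TPM by over 1.5 times: the B cell, megakaryocyte, endothelial and stromal, and stem lists.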

Other observations

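The tests in this part were chosen only after the results were seen, apart from the gene lists. Genes named in the next paragraph were picked after their values were seen, from the 20 most abundant nuclear protein-coding genes outside every list and outside the replication-dependent histones.

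Several abundant transcripts lay outside the lists. Cd24a, which encodes a surface glycoprotein of immature blood cells, had 708 ± 334 TPM (SD, n = 2), the highest of this set. Prdx2 and Gpx1, which encode enzymes that remove peroxides, had 300 ± 102 and 288 ± 108, and Car2, the carbonic anhydrase 2 gene, had 243 ± 55.5. Atpif1, an inhibitor of the mitochondrial ATP synthase, had 400 ± 91.6. Ctse, the cathepsin E gene, had 220 ± 74.8 and Hemgn, the hemogen gene, 166 ± 56.1. Chromosome and division genes Smc4 and Prc1 had 215 ± 62.8 and 193 ± 38.2.

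Some genes had many reads in one library and none in the other. Of the 123 such genes with a mean count of at least 50, 50 were at 0 in replicate 1 and 73 in replicate 2, with a median of 125 counts where reads were found. Lower depth of replicate 2 does not account for the pattern, since 59.3% of the genes were at 0 there, and sharing of reads between paralogs does not account for most of it, since 78.0% had a whole-number count (within 0.005). A candidate explanation is that few molecules were captured and each was read many times. The ratio of variance to mean grew 1.95-fold from mean counts of 10 to 30 up to 300 to 1000, while the coefficient of variation fell from 125% to 32.5%. In simulated counts that growth was 1.01-fold with fixed reads per molecule and 20.5-fold with a constant relative spread. The observed ratio kept rising, from 29.5 at 10 to 30 to 82.9 at 1000 to 3000. Fixed reads per molecule alone thus do not describe the spread, and the explanation remains a candidate. No biological explanation was tested, since the design has 1 group.

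Nuclear protein-coding genes had a lower TPM in replicate 2, by a median fold of 1.56 over 3384 genes. Over the same genes the median fold was 0.976 by counts over the library total, which is consistent with short RNAs, magnified by the length correction, taking a larger part of the TPM total in replicate 2. On the TPM scale not all classes of short RNA went that way. Small nuclear RNA genes rose from 19.6% of TPM in replicate 1 to 52.9% in replicate 2. Small nucleolar RNA genes fell from 21.1% to 8.65% of TPM, but rose from 0.263% to 0.484% of counts. Their fall in TPM lay largely in Gm22422, which went from 107258 to 5387 TPM. Short RNAs may also have been recovered better there: of 70 genes of 100 to 300 bases with a mean count of at least 1000, 84.3% were higher in replicate 2, including 31 of 31 small nuclear RNAs and 21 of 28 small nucleolar RNAs, with Gm22422 an exception at 47426 and 6553 counts. The small nuclear RNA genes in this set include near-identical copies that share reads, so they are not independent cases. Gm25679 and Gm22634, for example, had 17627.6 counts each in replicate 1. The 84.3% and the 31 of 31 therefore count some RNA species more than once. They do not give the share of distinct short RNAs that were higher in replicate 2. No biological explanation was tested.

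Kit was low in cells labelled CFU-E, beside abundant red cell membrane and granulocyte transcripts. No value in the tables decides between explanations of low Kit or of the granulocyte transcripts, and both stay open; the labels name no sort or gate. Whether the population was at a later stage than its name was not tested, since the design has no sample of another stage.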
